A study of Mus musculus with 8 samples.

How the data were processed

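Total kidney RNA (200 ng per sample, per the labels) was amplified in 1 round, labelled with 1 fluorescent dye and hybridised to 1-colour Agilent arrays, 4 samples with wild-type and 4 with Ccr2-/- marrow. Per the file headers and the submitters' processing notes, spots were extracted with Agilent Feature Extraction 10.7.3.1, and the deposited files hold spot intensity values on a linear scale: the raw mean and local background intensity and the intensity after background subtraction and spatial detrending by the software. Per the file headers, these values were not normalized between arrays. The submitters also deposited a value table of intensity values, 1 per probe. Set against the scanner values, it equals the mean processed signal times 1 factor per array (within 5% for at least 99.5% of bright probes), with a 75th percentile of 1500, a floor of 10 and no centring. Its column medians were 129, 138, 128 and 127 for wild-type 1 to 4 and 131, 132, 134 and 125 for Ccr2-/- 1 to 4.

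Processed signals were taken as log2 minus the array's 75th percentile over non-control spots. Control spots and spots the software marked as outliers (1.86% to 2.13% per array) were left out, and the 4 spots of a probe were averaged. A background subtraction leaves dim probes imprecise, so a probe was tested only if at least 50% of its spots were well above background on at least 4 of the 8 arrays, whatever their group; 10484 probes were left out and 28945 tested. A probe dim in most arrays is thus not analysed here. Gene names come from the array files, updated through the RefSeq table of GRCm38.p6, which matched 32047 probes; 7382 kept the file's name. Probe coordinates are those of the files, whose header names mm9; 9.11% of probes on the chromosome of their gene fell inside their gene's GRCm38.p6 span, and no coordinate of that build is printed. Different probes of a gene were tested apart, and for gene lists the tested probe with the highest mean over all arrays stood for its gene.

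Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with no covariate and Benjamini-Hochberg adjustment over all tested probes. Intervals at 95% use limma's SE and degrees of freedom. Gene lists with at least 4 measured members were tested two-sided with camera at a preset correlation of 0.01, with an estimated correlation and with fry, each adjusted over the 47 lists: immediate early and heat shock, mhc class ii presentation, adipocyte, erythroid, T cell, neutrophil, er stress, urothelium, lipogenesis, monocyte derived macrophage, collecting duct intercalated, extracellular matrix fibrosis, lipid uptake lxr foam cell, ccr2 ligands and chemokines, collecting duct principal, B and plasma cell, cytokine and nfkb inflammation, dendritic cell, NK and cytotoxic cell, resident macrophage, cholesterol synthesis srebp2, fatty acid oxidation peroxisome, smooth muscle, distal and connecting tubule, circadian clock, hypoxia response, amino acid and organic ion transport, p53 senescence, proximal tubule S1 S2, endothelium, mast cell basophil eosinophil, interferon response, complement, proximal tubule S3, fibroblast pericyte, androgen responsive male kidney, skeletal muscle, cell cycle proliferation, podocyte, apoptosis ferroptosis necroptosis, adrenal gland, Ccr2 chromosome neighbours, nrf2 antioxidant, oxidative phosphorylation, injured or failed repair tubule, renin angiotensin vasoactive, thick ascending limb. These lists, the tests and the naming rule were set before the data were examined. The rule names Ccr2 and Ldlr, then up to 12 genes in each direction with adjusted p under 0.05, non-overlapping groups and no clone name. A direction with fewer than 10 is filled to 10 by the smallest unadjusted p among genes with an absolute log2 change of at least 0.6 under the same conditions. From each list, up to 4 members with the smallest p were eligible. Single values were compared with exact permutation tests. The labels give the samples of a group as separate replicates without saying that each is a different mouse, so p-values measure only the spread between these samples, which may be technical. No 2 arrays held identical values (correlation at most 0.996). Figures were drawn with matplotlib 3.10.9.

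The probe test was tested on simulated data with 200 of 28945 probes changed, in 5 simulations of 4 against 4 arrays: it recovered 59.4% of changes of 1 and 91% of changes of 2 on the log2 scale, with 10.2 false calls per simulation. In 20 simulations on 21725 genes, the list test made 3 calls among unshifted lists in all and found a list shifted by 0.5 in all 20. Both kinds of simulation drew probes or genes independently, so they say nothing about probes, or lists whose genes, vary together between samples. The recovery rates therefore need not hold for these arrays. Alternatives were normexp background correction with an offset of 50, quantile and median scaling, the deposited value table, other filters on dim probes, a variance trend with robust estimation, array weights, slide or replicate number as a block, the mean of a gene's probes, and leaving out each array in turn. Values within slide 1 and slide 2, without both wild-type 2 and Ccr2-/- 3 and for lists without Ccr2 were added after seeing the data.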

Results

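Gene expression was measured in 8 samples of kidney RNA from male mice lacking the LDL receptor (LDLr-/-), a strain prone to high blood cholesterol on a fat-rich diet. All had been lethally irradiated, had received donor bone marrow, had undergone unilateral renal ischemia-reperfusion with 27 min of ischemia and had then eaten a high-fat diet for 3 weeks. The marrow came from wild-type donors in 4 samples and from Ccr2-/- donors in the other 4. Ccr2 is the receptor through which blood monocytes follow the chemokine Ccl2 out of the marrow and into tissue. The labels do not say whether the ischemic or the opposite kidney was sampled. Each sample was hybridised to 1 single-colour array. Of the array's probes, 68.7% to 77.4% were well above background on each array, and the number of arrays limits the precision. The comparison asked how the kidney's expression differed with the donors' Ccr2 genotype. Log2 values are relative to each array's 75th percentile, and every change is Ccr2-/- minus wild-type marrow.

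Ccr2 itself was far lower in kidneys of mice with Ccr2-/- marrow. Its probe (chromosome 9, 124022948 to 124023007 in mm9, sequence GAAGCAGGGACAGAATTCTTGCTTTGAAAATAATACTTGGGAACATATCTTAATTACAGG) read -0.016 ± 0.60 (SD, n = 4) with wild-type and -5.69 ± 0.94 (SD, n = 4) with Ccr2-/- marrow. The log2 change was -5.68 (95% interval -6.76 to -4.59), which is 51.2-fold lower, with adjusted p = 0.0201 by limma. All 4 Ccr2-/- arrays, at -7.08 to -5.09, lay below all wild-type arrays, at -0.46 to 0.88, and the exact permutation test gave two-sided p = 0.0286, the smallest that its 70 labelings allow. The probe stayed well above background on all 8 arrays. Which part of the gene the donors' allele lacks is not given in the sources used here, so it is open whether the probe lies in the deleted part. The probe's place in the gene's exons was not worked out, because no annotation of mm9 was used here. Ldlr, the gene inactivated in the recipients, differed by -0.42 (SE 0.25, limma adjusted p = 0.983; exact permutation p = 0.229). Whether the Ldlr probe lies in the inactivated part is unknown too.

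Among 28945 tested probes of 21725 genes, 4 passed adjusted p 0.05 in limma, 2 higher and 2 lower in the Ccr2-/- group. Ppfia4, which encodes a liprin scaffold protein, rose 7.10-fold, from -3.36 ± 0.14 to -0.53 ± 0.28 (SD, n = 4 each; limma adjusted p = 0.00102; chromosome 1, 136193361 to 136193420 in mm9). A second Ppfia4 probe, also well above background on all 8 arrays, gave -0.36 (SE 0.24), so the gene's probes disagreed. Spef2, a sperm flagellar gene, fell 1.98-fold at 1 of its 2 probes (log2 change -0.98, SE 0.092, limma adjusted p = 0.0337; chromosome 15, 9592491 to 9592550 in mm9), while the other gave -0.10 (SE 0.16). The clone-named gene 2310065F04Rik, outside the naming rule and chosen after its values were seen, was 5.97-fold higher (log2 change 2.58, SE 0.26, limma adjusted p = 0.0387; chromosome 11, 66925963 to 66926022 in mm9). It was well above background on 2 of 4 wild-type and 4 of 4 Ccr2-/- arrays. The plot of signal per array shows these genes.

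**Figure D1:**
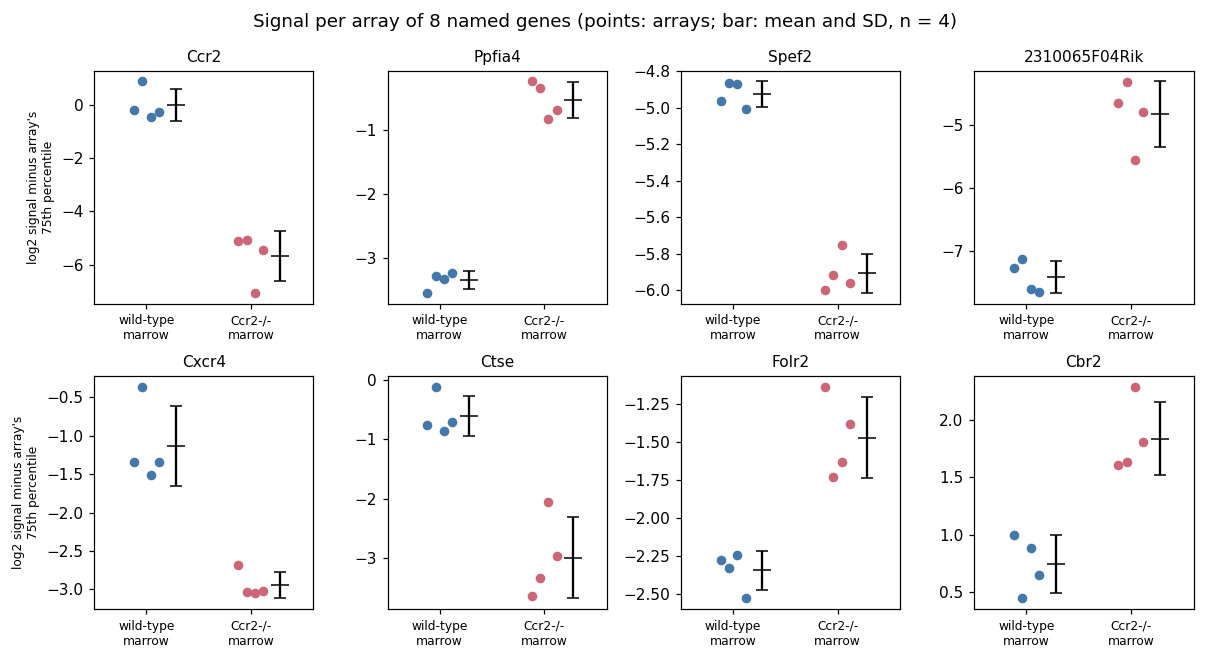
Signal per array of 8 named genes, as log2 signal minus the array's 75th percentile on the y axis, for 4 arrays of each group (points), with mean and SD beside them. The groups do not overlap in any of the 8, which was a condition for naming Cxcr4, Ctse, Folr2 and Cbr2. These last 4 did not pass adjusted p 0.05.

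Arrays fell on 3 slides, each scanned apart: slide 1 held wild-type 1 and Ccr2-/- 1 and 2, slide 2 held wild-type 3 and 4 and Ccr2-/- 3 and 4, and slide 3 held wild-type 2 alone. With slide as a block, no probe passed (lowest limma adjusted p = 0.0570, 856 probes at unadjusted p under 0.05). Ccr2 was then -5.51, with -4.90 within slide 1 and -5.91 within slide 2. The corresponding values were 2.82, 3.26 and 2.53 for Ppfia4, -0.95, -0.998 and -0.92 for Spef2, and 2.58, 2.78 and 2.45 for 2310065F04Rik. With normexp, Spef2 was -0.53 (limma adjusted p = 0.248) and 2310065F04Rik 1.34 (limma adjusted p = 0.0679), so both calls ended. Both calls also ended with the deposited value table (limma adjusted p = 0.0677 each) and with no filter on dim probes (0.0967 each). They ended too with replicate number as a block (0.370 and 0.0535), where that of Ppfia4 ended as well (0.0535). With the mean of a gene's probes only Ccr2 was called, so the calls of Ppfia4, Spef2 and 2310065F04Rik all ended. The Spef2 call ended with a variance trend and robust estimation (0.194) and without both wild-type 2 and Ccr2-/- 3 (0.0506), and that of 2310065F04Rik with quantile scaling (0.0598). Leaving out any single array except Ccr2-/- 3 ended the call of Ccr2 (log2 change -5.88 to -5.22, limma adjusted p 0.00453 to 0.150 over the 8 arrays left out). Spef2 and 2310065F04Rik also passed only without Ccr2-/- 3 (adjusted p 0.0311 to 0.271 and 0.00453 to 0.271), whereas Ppfia4 passed each time (adjusted p 0.00196 to 0.0127). Over all tested probes, 715 had an unadjusted p under 0.05 where 1447 would by chance, and 538 had groups that did not overlap where chance gives 827, a share of 2.86%.

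No other gene passed, and the next genes by the naming rule are given as values. In the lower direction they were Cxcr4 -1.81 (SE 0.24) for the receptor of Cxcl12, Ctse -2.38 (SE 0.33) for cathepsin E, Dcstamp -1.40 (SE 0.21) for a protein of macrophage fusion, Cd209e -2.38 (SE 0.34) for a C-type lectin, Dpep2 -1.30 (SE 0.21) for a dipeptidase, Skint3 -2.35 (SE 0.36), Galnt9 -1.84 (SE 0.27) and Spink2 -2.01 (SE 0.29). Their limma adjusted p-values lay between 0.269 and 0.398, so none passed. That their groups did not overlap was a condition of the naming rule and adds no support. Cxcr4 passed without wild-type 2 (-1.55, adjusted p = 0.0321), and Ctse without Ccr2-/- 3 (-2.69, adjusted p = 0.0273) and without both of these arrays (-2.53, adjusted p = 0.0306). With array weights Cxcr4, Ctse, Cd209e, Spink2, Fpr1 and Gsdmc4 passed, the last 2 of them higher. Cd209e was well above background on 1 of 4 Ccr2-/- arrays and Spink2 on 3 of 4, so these values are approximate. In the higher direction, the values were Fpr1 1.29 (SE 0.20) for the formyl peptide receptor, Cxcr1 0.92 (SE 0.18) for a neutrophil chemokine receptor, Folr2 0.87 (SE 0.15) for a folate receptor of tissue macrophages, Cbr2 1.09 (SE 0.19) for carbonyl reductase 2, Msln 0.84 (SE 0.14) for mesothelin, Gsdmc4 0.89 (SE 0.13) for a gasdermin, Fam83e 0.74 (SE 0.13), Itprid1 1.13 (SE 0.20) and Iqsec1 0.62 (SE 0.11). These too did not pass (limma adjusted p 0.290 to 0.538). Cxcr1 and Itprid1 were each well above background on 1 of 4 wild-type arrays, and Iqsec1 on 3 of 4, so the values of these 3 are approximate too. A second, brighter Iqsec1 probe gave 0.18 (SE 0.15) and a second Fam83e probe 0.40 (SE 0.17), both with groups that overlapped.

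By a set test that takes genes as nearly independent, but not by one that estimates their correlation, gene lists differed with the marrow. Those with lower values on the whole were markers of T cells, NK cells, dendritic cells and resident macrophages, MHC class II genes, chemokine and cytokine genes, lipid uptake genes, matrix genes and stress-response genes. Those with higher values on the whole were markers of neutrophils, B cells, erythroid cells, adipocytes, collecting duct and urothelium and genes of lipogenesis, cholesterol synthesis and fatty acid oxidation. Of the 47 gene lists fixed before the data were examined, 22 passed adjusted p 0.05 in camera with a preset correlation of 0.01, 10 higher and 12 lower in the Ccr2-/- group. No list passed with an estimated correlation (lowest adjusted p = 0.398, 2 at unadjusted p under 0.05) or in the directional fry test (lowest adjusted p = 0.384, 3 at unadjusted p under 0.05). In fry's test for change in either direction 1 list passed, that of monocyte-derived macrophages, which holds Ccr2 (adjusted p = 0.000878). With Ccr2 itself left out of its list, a choice made after seeing the data, 21 lists passed camera. None then passed fry's test for change in either direction (lowest adjusted p = 0.517, 2 at unadjusted p under 0.05). Ccr2 was the only list member that passed over all genes tested, and members passed adjusted over the list alone only in the monocyte-derived macrophage, dendritic cell, immediate early and heat shock, adipocyte and erythroid lists. Without Ccr2-/- 3, 13 lists passed, of which 8 were among the 22. Within slide 1, 1 wild-type array stood against 2 Ccr2-/- arrays. Values of single members are log2 changes with the SE from limma.

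In the monocyte-derived macrophage list, 7 of the 11 measured members were lower in the Ccr2-/- group (median log2 change -0.075; adjusted p = 0.00353 by camera, adjusted p = 0.555 with an estimated correlation). The median was -0.031 with slide as a block, -0.018 within slide 1 and -0.039 within slide 2, and the camera call ended without Ccr2-/- 3 (median -0.0092, adjusted p = 0.0676), with array weights (median 0.0049, adjusted p = 0.153) or without both wild-type 2 and Ccr2-/- 3 (median 0.0028, adjusted p = 0.127). Without wild-type 1 the median was -0.13, without wild-type 2 -0.0092, without wild-type 3 -0.13, without Ccr2-/- 1 -0.21, with normexp -0.022 and with the mean of a gene's probes -0.16, and the call held. This call rests on Ccr2, the gene that the donors lack: without it, 6 of the 10 other members were lower (median -0.045, mean -0.23) and the list did not pass camera (adjusted p = 0.113). Besides Ccr2, the coagulation factor X gene F10 fell adjusted over the list alone (log2 change -1.73, SE 0.32, limma adjusted p = 0.00283), while Arg1 was 0.60 (SE 0.34) and Chil3 -0.66 (SE 0.40). Among dendritic cell markers, 9 of the 12 measured members were lower in the Ccr2-/- group (median log2 change -0.12; adjusted p = 0.00702 by camera, adjusted p = 0.720 with an estimated correlation). The median was -0.14 with slide as a block, 0.10 within slide 1 and -0.39 within slide 2, and the camera call ended without Ccr2-/- 3 (median -0.039, adjusted p = 0.237), without Ccr2-/- 4 (median -0.012, adjusted p = 0.189), with array weights (median 0.049, adjusted p = 0.901) or without both wild-type 2 and Ccr2-/- 3 (median 0.028, adjusted p = 0.644). Without wild-type 2 the median was -0.068, without Ccr2-/- 1 -0.28 and without Ccr2-/- 2 -0.20, and the call held. The integrin gene Itgax fell adjusted over the list alone (log2 change -1.03, SE 0.22, limma adjusted p = 0.0149), and Cd209a was -1.51 (SE 0.49). For resident macrophage markers, 12 of the 13 measured members were lower in the Ccr2-/- group (median log2 change -0.11; adjusted p = 0.0114 by camera, adjusted p = 0.738 with an estimated correlation). The median was -0.10 with slide as a block, 0.12 within slide 1 and -0.27 within slide 2, and the camera call ended without wild-type 2 (median -0.055, adjusted p = 0.0721), without Ccr2-/- 3 (median 0.022, adjusted p = 0.886), with array weights (median -0.027, adjusted p = 0.995) or without both wild-type 2 and Ccr2-/- 3 (median 0.030, adjusted p = 0.453). Without Ccr2-/- 1 the median was -0.21, and the call held. Lyz2 was -0.61 (SE 0.24) and Cd81 -0.11 (SE 0.080). In the MHC class II presentation list, all 11 measured members were lower in the Ccr2-/- group (median log2 change -0.33; adjusted p = 6.13e-07 by camera, adjusted p = 0.568 with an estimated correlation). The median was -0.33 with slide as a block, -0.00069 within slide 1 and -0.57 within slide 2. Without Ccr2-/- 1 the median was -0.52, without Ccr2-/- 3 -0.18, with array weights -0.14 and without both wild-type 2 and Ccr2-/- 3 -0.14, and the call held. Examples were Ctss -0.38 (SE 0.17), H2-Aa -0.43 (SE 0.22) and H2-Ab1 -0.22 (SE 0.11). In the lipid uptake and foam cell list, 16 of the 18 measured members were lower in the Ccr2-/- group (median log2 change -0.20; adjusted p = 0.00420 by camera, adjusted p = 0.555 with an estimated correlation). The median was -0.12 with slide as a block, 0.076 within slide 1 and -0.26 within slide 2, and the camera call ended without Ccr2-/- 3 (median -0.084, adjusted p = 0.127) or without both wild-type 2 and Ccr2-/- 3 (median -0.034, adjusted p = 0.353). Without wild-type 2 the median was -0.10 and with array weights -0.070, and the call held. Abcg1, a cholesterol exporter, was -0.30 (SE 0.13), and Soat1 -0.29 (SE 0.15).

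Of neutrophil markers, 8 of the 11 measured members were higher in the Ccr2-/- group (median log2 change 0.32; adjusted p = 0.000420 by camera, adjusted p = 0.398 with an estimated correlation). The median was 0.30 with slide as a block, 0.26 within slide 1 and 0.26 within slide 2. Without wild-type 3 the median was 0.20 and without Ccr2-/- 3 0.54, and the call held. Members with the smallest p were Retnlg 1.69 (SE 0.52), S100a9 1.13 (SE 0.40) and Camp 0.77 (SE 0.28), none of which passed adjusted over the list alone. For T cell markers, all 13 measured members were lower in the Ccr2-/- group (median log2 change -0.28; adjusted p = 1.85e-05 by camera, adjusted p = 0.574 with an estimated correlation). The median was -0.33 with slide as a block, 0.23 within slide 1 and -0.81 within slide 2. Without Ccr2-/- 1 the median was -0.44 and without Ccr2-/- 4 -0.14, and the call held. Il7r was -0.82 (SE 0.34), Lat -0.49 (SE 0.23) and Cd5 -0.49 (SE 0.23). As for NK and cytotoxic cell markers, 7 of the 11 measured members were lower in the Ccr2-/- group (median log2 change -0.26; adjusted p = 0.0106 by camera, adjusted p = 0.720 with an estimated correlation). The median was -0.22 with slide as a block, 0.43 within slide 1 and -0.80 within slide 2, and the camera call ended without wild-type 3 (median -0.23, adjusted p = 0.334), without Ccr2-/- 4 (median -0.16, adjusted p = 0.584) or without both wild-type 2 and Ccr2-/- 3 (median -0.13, adjusted p = 0.135). Without Ccr2-/- 3 the median was -0.13, and the call held. Klrk1 was -0.92 (SE 0.50, well above background on 3 of 4 Ccr2-/- arrays) and Klrd1 -0.73 (SE 0.35). Of B and plasma cell markers, 8 of the 10 measured members were higher in the Ccr2-/- group (median log2 change 0.16; adjusted p = 0.00678 by camera, adjusted p = 0.555 with an estimated correlation). The median was 0.17 with slide as a block, 0.085 within slide 1 and 0.36 within slide 2, and the camera call ended without Ccr2-/- 3 (median 0.12, adjusted p = 0.237), with array weights (median 0.054, adjusted p = 0.170) or without both wild-type 2 and Ccr2-/- 3 (median 0.044, adjusted p = 0.516). Without Ccr2-/- 1 the median was 0.27 and without Ccr2-/- 4 0.31, and the call held. Cd19 was 0.58 (SE 0.21), Fcmr 0.54 (SE 0.18) and Ms4a1 0.53 (SE 0.16).

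In the list of Ccr2 ligands and other chemokines, 16 of the 20 measured members were lower in the Ccr2-/- group (median log2 change -0.15; adjusted p = 0.00422 by camera, adjusted p = 0.720 with an estimated correlation). The median was -0.15 with slide as a block, 0.30 within slide 1 and -0.44 within slide 2, and the camera call ended without Ccr2-/- 3 (median -0.10, adjusted p = 0.636), with array weights (median -0.015, adjusted p = 0.275) or without both wild-type 2 and Ccr2-/- 3 (median 0.031, adjusted p above 0.9). Without wild-type 3 the median was -0.094, and the call held. Ccl9 was -0.98 (SE 0.28) and Ccl6 -0.87 (SE 0.26), while Ccl8 was 0.55 (SE 0.20). For cytokine and NF-kB genes, 17 of the 21 measured members were lower in the Ccr2-/- group (median log2 change -0.13; adjusted p = 0.00702 by camera, adjusted p = 0.720 with an estimated correlation). The median was -0.11 with slide as a block, 0.22 within slide 1 and -0.39 within slide 2, and the camera call ended without wild-type 2 (median -0.077, adjusted p = 0.126), without Ccr2-/- 3 (median -0.058, adjusted p = 0.546), with array weights (median -0.013, adjusted p = 0.680) or without both wild-type 2 and Ccr2-/- 3 (median 0.019, adjusted p = 0.624). Without wild-type 1 the median was -0.21, without Ccr2-/- 1 -0.28 and without Ccr2-/- 2 -0.20, and the call held. Il1b was -0.94 (SE 0.52) and Saa3 0.62 (SE 0.33). Among immediate early and heat shock genes, 13 of the 14 measured members were lower in the Ccr2-/- group (median log2 change -0.32; adjusted p = 4.48e-08 by camera, adjusted p = 0.472 with an estimated correlation). The median was -0.40 with slide as a block, -0.10 within slide 1 and -0.47 within slide 2. Without Ccr2-/- 3 the median was -0.17 and with array weights -0.21, and the call held. Hspa1a, which encodes an inducible heat shock protein, fell adjusted over the list alone (log2 change -0.86, SE 0.20, limma adjusted p = 0.0324), and Fos was -0.54 (SE 0.18) and Hsph1 -0.37 (SE 0.14). In the endoplasmic reticulum stress list, 11 of the 12 measured members were lower in the Ccr2-/- group (median log2 change -0.14; adjusted p = 0.000652 by camera, adjusted p = 0.599 with an estimated correlation). The median was -0.11 with slide as a block, 0.12 within slide 1 and -0.33 within slide 2, and the camera call ended without Ccr2-/- 3 (median -0.072, adjusted p = 0.0636) or without both wild-type 2 and Ccr2-/- 3 (median -0.035, adjusted p = 0.119). Herpud1 was -0.42 (SE 0.12) and Dnajb9 -0.36 (SE 0.15). Of the matrix and fibrosis genes, 22 of the 25 measured members were lower in the Ccr2-/- group (median log2 change -0.21; adjusted p = 0.00408 by camera, adjusted p = 0.865 with an estimated correlation). The median was -0.14 with slide as a block, 0.35 within slide 1 and -0.53 within slide 2, and the camera call ended without wild-type 2 (median -0.085, adjusted p = 0.0846), without Ccr2-/- 3 (median 0.090, adjusted p = 0.219) or with array weights (median 0.11, adjusted p = 0.0726); the list was called in the opposite direction without both wild-type 2 and Ccr2-/- 3 (median 0.17, adjusted p = 0.000916). Without Ccr2-/- 1 the median was -0.42, and the call held. Tgfbi was -0.44 (SE 0.18) and Mmp14 -0.31 (SE 0.19).

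In the adipocyte list, all 8 measured members were higher in the Ccr2-/- group (median log2 change 1.82; adjusted p = 6.13e-07 by camera, adjusted p = 0.555 with an estimated correlation). The median was 2.48 with slide as a block, 1.05 within slide 1 and 3.42 within slide 2. With array weights the median was 0.97, and the call held. Cfd, Adipoq and Cidec rose adjusted over the list alone. The values were Cfd 4.13 (SE 0.97) for the protease adipsin, Adipoq 3.73 (SE 1.00, well above background on 2 of 4 wild-type arrays) for adiponectin and Cidec 2.58 (SE 0.86, well above background on 2 of 4 wild-type arrays) for a lipid droplet protein. Retn was 2.29 (SE 0.98). The list's mean, centred per gene, was 2.46 in Ccr2-/- 3, 2.28 in Ccr2-/- 4, 0.10 in Ccr2-/- 2 and -0.88 in Ccr2-/- 1, against -1.50 to -0.48 with wild-type marrow. For erythroid genes, all 7 measured members were higher in the Ccr2-/- group (median log2 change 0.98; adjusted p = 6.64e-06 by camera, adjusted p = 0.555 with an estimated correlation). The median was 0.82 with slide as a block, 0.91 within slide 1 and 0.88 within slide 2. Without both wild-type 2 and Ccr2-/- 3 the median was 0.57, and the call held. The rise was not shared by every array. The erythroid list's mean, centred per gene, was -0.43, 0.64, 1.15 and 0.34 in Ccr2-/- 1 to 4. In wild-type 1 to 4 it was -0.28, -1.07, -0.023 and -0.33, so Ccr2-/- 1 lay below wild-type 1, 3 and 4. The groups' means did not differ by the exact permutation test (p = 0.114, 0.767 adjusted over all lists). The 4 members that rose adjusted over the list alone were Alas2 1.35 (SE 0.39), Hba-a1 0.97 (SE 0.30), Hbb-bt 1.06 (SE 0.37) and Hbb-b1 0.98 (SE 0.36). Of lipogenesis genes, 11 of the 12 measured members were higher in the Ccr2-/- group (median log2 change 0.18; adjusted p = 0.00155 by camera, adjusted p = 0.621 with an estimated correlation). The median was 0.16 with slide as a block, 0.058 within slide 1 and 0.27 within slide 2, and the camera call ended without Ccr2-/- 3 (median 0.11, adjusted p = 0.0676), with array weights (median -0.0034, adjusted p = 0.995) or without both wild-type 2 and Ccr2-/- 3 (median 0.056, adjusted p = 0.624). Thrsp, shared with the adipocyte list, was 0.92 (SE 0.47), and Pnpla3 0.44 (SE 0.23, well above background on 3 of 4 wild-type arrays). In the cholesterol synthesis list, 15 of the 18 measured members were higher in the Ccr2-/- group (median log2 change 0.10; adjusted p = 0.0309 by camera, adjusted p = 0.720 with an estimated correlation). The median was 0.023 with slide as a block, where the call ended (adjusted p = 0.512 by camera), -0.12 within slide 1 and 0.19 within slide 2, and the camera call ended without wild-type 2 (median 0.016, adjusted p = 0.537), without wild-type 3 (median 0.13, adjusted p = 0.0631), without Ccr2-/- 1 (median 0.12, adjusted p = 0.0690), without Ccr2-/- 3 (median 0.085, adjusted p = 0.161), without Ccr2-/- 4 (median 0.069, adjusted p = 0.192), with normexp (median 0.11, adjusted p = 0.0823), with array weights (median 0.012, adjusted p = 0.995), with the mean of a gene's probes (median 0.073, adjusted p = 0.138) or without both wild-type 2 and Ccr2-/- 3 (median -0.0022, adjusted p above 0.9). Without wild-type 1 the median was 0.17, and the call held. Pcsk9 was 0.48 (SE 0.17) and Fdft1 0.22 (SE 0.14). For fatty acid oxidation and peroxisome genes, 20 of the 22 measured members were higher in the Ccr2-/- group (median log2 change 0.16; adjusted p = 0.0310 by camera, adjusted p = 0.865 with an estimated correlation). The median was 0.024 with slide as a block, where the call ended (adjusted p = 0.690 by camera), -0.48 within slide 1 and 0.37 within slide 2, and the camera call ended without wild-type 2 (median 0.011, adjusted p = 0.924), without wild-type 4 (median 0.12, adjusted p = 0.253), without Ccr2-/- 3 (median 0.071, adjusted p = 0.886), without Ccr2-/- 4 (median 0.12, adjusted p = 0.234) or with normexp (median 0.17, adjusted p = 0.107); the list was called in the opposite direction with array weights (median -0.16, adjusted p = 0.00309) and without both wild-type 2 and Ccr2-/- 3 (median -0.11, adjusted p = 0.0198). Without wild-type 1 the median was 0.29, and the call held. Hmgcs2 was 0.51 (SE 0.30) and Cyp4a14 0.99 (SE 0.66).

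Among principal cell markers of the collecting duct, 9 of the 10 measured members were higher in the Ccr2-/- group (median log2 change 0.65; adjusted p = 0.00422 by camera, adjusted p = 0.720 with an estimated correlation). The median was 0.52 with slide as a block, -0.63 within slide 1 and 1.38 within slide 2, and the camera call ended without Ccr2-/- 3 (median 0.051, adjusted p = 0.750), with array weights (median 0.067, adjusted p = 0.425) or without both wild-type 2 and Ccr2-/- 3 (median -0.18, adjusted p = 0.568). Elf5 was 1.38 (SE 0.69), Aqp4 0.98 (SE 0.55) and Fxyd4 0.70 (SE 0.38). The list's mean was 2.13 in Ccr2-/- 3 and between -0.93 and 0.31 on the other 7 arrays. Of intercalated cell markers, all 10 measured members were higher in the Ccr2-/- group (median log2 change 0.45; adjusted p = 0.00392 by camera, adjusted p = 0.720 with an estimated correlation). The median was 0.38 with slide as a block, -0.55 within slide 1 and 0.93 within slide 2, and the camera call ended without Ccr2-/- 3 (median 0.043, adjusted p = 0.736), with array weights (median 0.041, adjusted p = 0.680) or without both wild-type 2 and Ccr2-/- 3 (median -0.027, adjusted p = 0.560). Without wild-type 2 the median was 0.30, and the call held. Foxi1 was 0.52 (SE 0.27) and Kit 0.29 (SE 0.22). For urothelium markers, 7 of the 8 measured members were higher in the Ccr2-/- group (median log2 change 0.68; adjusted p = 0.000773 by camera, adjusted p = 0.574 with an estimated correlation). The median was 0.53 with slide as a block, -0.082 within slide 1 and 1.07 within slide 2, and the camera call ended with array weights (median 0.10, adjusted p = 0.263) or without both wild-type 2 and Ccr2-/- 3 (median 0.13, adjusted p = 0.131). Without wild-type 2 the median was 0.44 and without Ccr2-/- 3 0.32, and the call held. Upk3a was 0.89 (SE 0.33) and Upk1b 0.98 (SE 0.36).

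**Figure D2:**
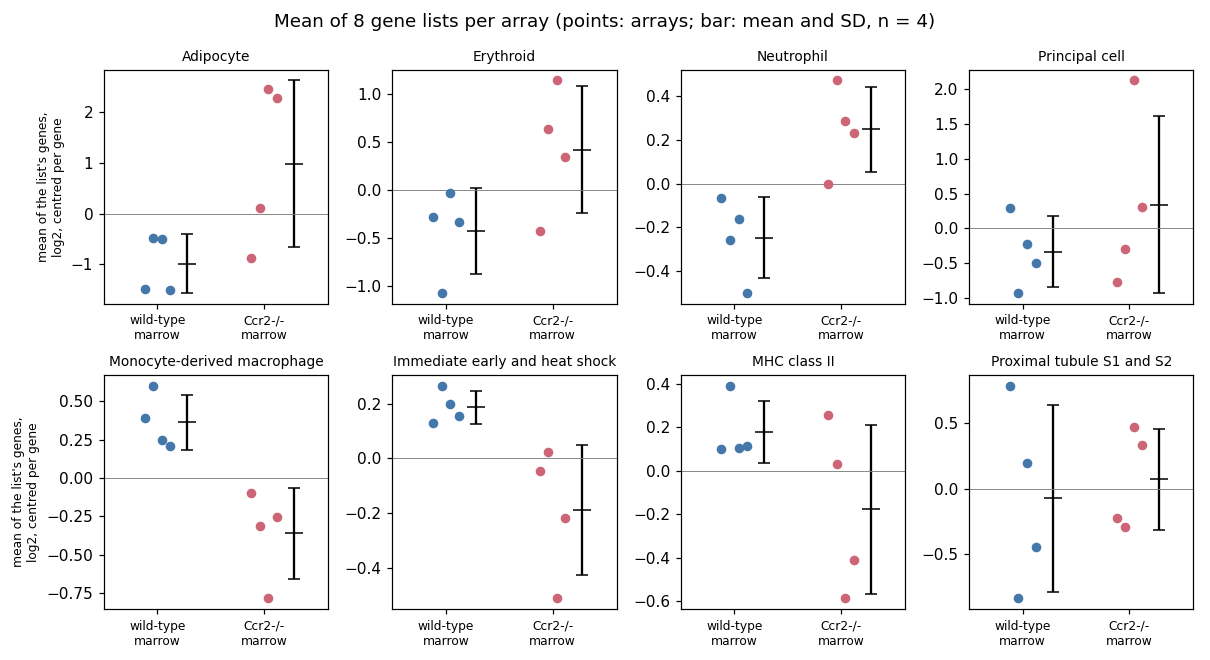
Mean of 8 gene lists per array, on the log2 scale after centring each gene on its mean over the 8 arrays (y axis), for 4 arrays of each group (points), with mean and SD beside them. Adipocyte genes were highest in Ccr2-/- 3 and 4 (2.46 and 2.28), principal cell genes in Ccr2-/- 3 (2.13).

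The other 25 lists did not pass camera, and no member of them passed over all genes or adjusted over the list alone. Among the nephron lists were proximal tubule S1 and S2 (16 measured, 14 higher, median 0.16, adjusted p = 0.269), proximal tubule S3 (10 measured, 4 higher, median -0.051, adjusted p = 0.564), thick ascending limb (10 measured, 5 higher, median 0.032, adjusted p = 0.860), distal and connecting tubule (10 measured, 9 higher, median 0.42, adjusted p = 0.140), podocyte (10 measured, 8 higher, median 0.028, adjusted p = 0.684) and injured or poorly repaired tubule (20 measured, 12 higher, median 0.028, adjusted p = 0.860). Tubule examples were Slc34a1 0.18 (SE 0.27), Slc7a13 -0.45 (SE 0.57) and Slc12a1 -0.26 (SE 0.19), the podocyte gene Nphs2 was 0.22 (SE 0.12), and the injury-associated genes Krt18, Lcn2 and Sox9 were 0.24 (SE 0.11), 0.21 (SE 0.12) and -0.48 (SE 0.24). Lists of other cells and tissues were endothelium (12 measured, 4 higher, median -0.035, adjusted p = 0.364), fibroblast and pericyte (12 measured, 4 higher, median -0.10, adjusted p = 0.569), smooth muscle (7 measured, 6 higher, median 0.22, adjusted p = 0.0812), skeletal muscle (8 measured, 4 higher, median 0.015, adjusted p = 0.575), adrenal gland (6 measured, 3 higher, median -0.017, adjusted p = 0.860) and mast cell, basophil and eosinophil (6 measured, 2 higher, median -0.15, adjusted p = 0.471). Immune, stress and growth lists were interferon response (20 measured, 14 higher, median 0.087, adjusted p = 0.552), complement (16 measured, 7 higher, median -0.051, adjusted p = 0.555), chromosomal neighbours of Ccr2 (19 measured, 9 higher, median -0.025, adjusted p = 0.860), cell cycle (18 measured, 10 higher, median 0.020, adjusted p = 0.617), cell death (14 measured, 8 higher, median 0.012, adjusted p = 0.860), p53 and senescence (13 measured, 3 higher, median -0.033, adjusted p = 0.254), hypoxia (15 measured, 10 higher, median 0.071, adjusted p = 0.211) and Nrf2 antioxidant (13 measured, 8 higher, median 0.050, adjusted p = 0.860). The remaining lists were oxidative phosphorylation (20 measured, 11 higher, median 0.068, adjusted p = 0.860), amino acid and organic ion transport (17 measured, 16 higher, median 0.13, adjusted p = 0.254), androgen-responsive kidney (11 measured, 3 higher, median -0.050, adjusted p = 0.575), circadian clock (15 measured, 7 higher, median -0.0016, adjusted p = 0.198) and renin-angiotensin and vasoactive (11 measured, 6 higher, median 0.013, adjusted p = 0.860). For the thick ascending limb, adrenal, cell cycle and Nrf2 lists the median and the direction of camera's test differed in sign.

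Over the whole profile, the groups accounted for 13.8% of the variance, and 13 of the 35 splits of the 8 arrays into groups of 4 gave as much (exact permutation p = 0.371). The first component held 45.7% of the variance, with wild-type 2 at 78.5 and Ccr2-/- 3 at -56.4 at its ends and the other 6 arrays between. Wild-type 2 lay alone on its slide and had the brightest 75th percentile of signal, 7804 against 4419 to 5290 on the other arrays. The genes of the proximal tubule S1 and S2 list averaged -0.84 on wild-type 2 and 0.79 on wild-type 1.

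**Figure D3:**
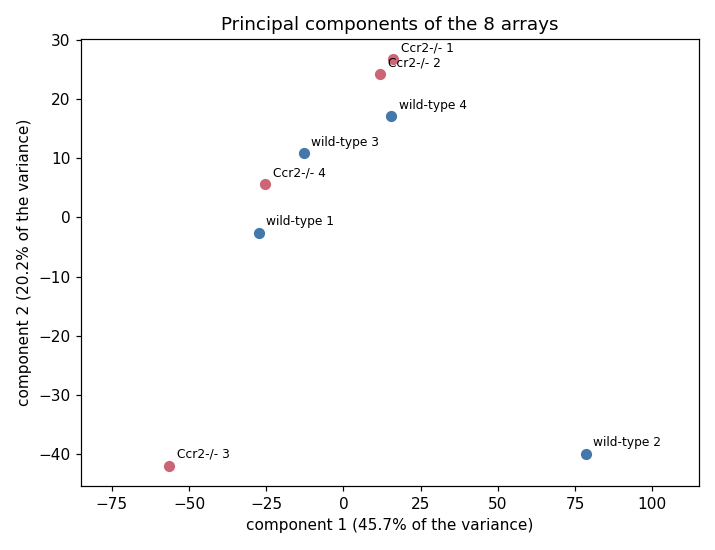
Position of the 8 arrays on the first (x axis) and second (y axis) principal components of the tested probes, in log2 units, blue for wild-type and red for Ccr2-/- marrow. The groups overlap, and wild-type 2 and Ccr2-/- 3 lie at opposite ends of the first component, at 78.5 and -56.4.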

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

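The tests of other splits of the arrays, of the chromosome 1 genes, of single arrays and of slide were chosen only after the results were seen. Of 278 sets of 4 values tested with Dixon's criterion, 7 held 1 array far from the other 3 of its group, where chance gives about 1 in 20. On wild-type 2, Cxcr4 read -0.36 against -1.51 to -1.34 on the other wild-type arrays, and on Ccr2-/- 1 it read -2.69 against -3.04 to -3.02 on the other Ccr2-/- arrays. Dpep2 read -2.39 against -2.69 to -2.64 and Pcsk9 -2.93 against -2.47 to -2.42 on wild-type 2 and on the other wild-type arrays. The mean of the MHC class II list, centred per gene, was 0.39 against 0.10 to 0.11 on the same arrays. The endoplasmic reticulum stress list averaged -0.16 on wild-type 1, with 0.14 to 0.19 on the other wild-type arrays. The negative control spots of Ccr2-/- 4 had a mean net signal of 44.5 against 28.1 to 29.2 on the other Ccr2-/- arrays.

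Chance is not excluded for either count of calls. Of the 35 splits of the 8 arrays into groups of 4, 2 called at least the 4 genes of the real one. The other, wild-type 1 and 3 with Ccr2-/- 3 and 4 against the rest, called 406, many times the real number. It parts the arrays by the sign of the first principal component, so it restates that component and is no separate observation. Both show a structure of the samples that the marrow does not explain. For gene lists, 13 of the 35 splits called at least the 22 of the real one, and the highest other called 35.

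Many of the list shifts followed single arrays. With slide as a block, 20 of the 22 called lists kept their call and direction, so an offset between slides was not needed for those calls. That block gives no weight to wild-type 2, alone on its slide, and the calls kept are those of camera, for which chance is not excluded. Within slide 2, 21 were called in the same direction; slide 1 holds 1 wild-type array, whose own deviation could set every difference there, so its calls (none in the same direction, 7 in the opposite one) decide nothing. Slide 2 holds Ccr2-/- 3, so the calls within it cannot be told apart from a deviation of that array. The 1 array Ccr2-/- 3 is a candidate source of part of the list shifts, as 8 of the 22 lists kept their call without it. Of the 22, 9 kept call and direction with array weights (1 called the opposite way) and 6 without both wild-type 2 and Ccr2-/- 3 (2 the opposite way). Fat tissue on some of the kidney pieces may account for the adipocyte genes: a second list of 9 adipocyte genes followed the first over the 8 arrays (Pearson r = 0.963, exact permutation p = 0.00298; Spearman rho = 0.714, exact permutation p = 0.0576; 1 relation computed), but among the 6 arrays other than Ccr2-/- 3 and 4, which stood apart, r was 0.712 (exact permutation p = 0.138), so it rests on those 2 arrays and stays open. Fat attached to the kidney, fat cells within it and an effect of the marrow were not told apart by any test.

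The genes Cxcr4, Ctse and Ppfia4, which have small p-values, lie close together, at 130485079, 133571990 and 136193361 on chromosome 1 in mm9. A rise of every Ppfia4 transcript is argued against by the gene's second probe, at -0.36. Chance placement stays open: of 10000 random placements, a share of 0.00730 put as many of the 9 genes with unadjusted p under 0.0001 within 10 Mb, but with the 42 genes under 0.001 the share was 0.548, and the stricter limit was chosen with the genes in view. A segment of another strain carried by the donors stays open too, as its test did not decide. Of 170 other genes within 10 Mb, 5.88% had an unadjusted p under 0.05, where all genes gave 3.06%. That share was above 91.4% of 105 other places, so the remaining places reached at least as much. A narrower region gave 6.92%, above 94.2% of 171 places, but it lies inside the first and is no separate observation. The chromosomal neighbours of Ccr2 did not shift as a list (19 measured, 9 higher, median -0.025, adjusted p = 0.860 by camera). They lie on chromosome 9, so they do not test a segment on chromosome 1. An effect of Ccr2 loss on Cxcr4, Ctse and Ppfia4 was not tested apart from the donors' other differences.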

How the results depend on the processing

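The within-slide values, the fits without both wild-type 2 and Ccr2-/- 3 and the lists without Ccr2 were chosen after seeing the data. The 4 genes called numbered 2 with normexp, 2 with the deposited value table, 2 with no filter on dim probes, 1 with the mean of a gene's probes, 13 with array weights, 0 with slide as a block, 0 within slide 1 and 0 within slide 2 (856, 5106 and 2162 at unadjusted p under 0.05 in limma), and 1 to 5 when 1 array was left out. With fewer arrays or more terms, the fits have fewer degrees of freedom; otherwise the cause was not tested. The replicate numbers did not pair the samples (correlations of deviations -0.36, 0.30, 0.20 and -0.10), and the replicate block left 1 call. Ccr2 stayed lower throughout, -4.72 with normexp, -5.51 with slide as a block (limma adjusted p = 0.0792), -4.90 and -5.91 within the slides and -5.88 to -5.22 with 1 array left out; its adjusted p ranged from 0.000362 to 0.196 over all alternatives. In alternatives that kept all 8 arrays or left out more than 1, other genes named gave 1108 values on the same side of the threshold. A further 21 lost and 7 gained a call, 30 changed sign with no call on either side, and none reversed with a call. The mean of a gene's probes is not in these counts. With it only Ccr2 was called, so Ppfia4, Spef2 and 2310065F04Rik also lost their calls. The group share of variance was 13.3% to 19.3% with 1 array left out, and no alternative passed. The 22 called lists became 0 with an estimated correlation, which allows for genes that vary together, 0 with directional fry, which also tests against no change rather than against other genes (2 and 3 at unadjusted p under 0.05), 21 with Ccr2 left out of its list, and 13 to 28 with 1 array left out. In all alternatives other than leaving out 1 array, 75 list values lost and 38 gained a call. These counts include the calls lost with an estimated correlation, with fry and without Ccr2. Only lists that turned direction and were called in the main fit or in the alternative are named next. With their median log2 change, they were proximal tubule S1 S2 -0.31, fibroblast pericyte 0.17, resident macrophage -0.027, dendritic cell 0.049, extracellular matrix fibrosis 0.11, oxidative phosphorylation -0.10, fatty acid oxidation peroxisome -0.16, lipogenesis -0.0034 and amino acid and organic ion transport -0.21 with array weights. Within slide 1 they were proximal tubule S1 S2 -0.83, distal and connecting tubule -0.85, collecting duct principal -0.63, collecting duct intercalated -0.55, fibroblast pericyte 0.34, resident macrophage 0.12, dendritic cell 0.10, T cell 0.23, NK and cytotoxic cell 0.43, urothelium -0.082, ccr2 ligands and chemokines 0.30, cytokine and nfkb inflammation 0.22, complement 0.23, mhc class ii presentation -0.00069, extracellular matrix fibrosis 0.35, oxidative phosphorylation -0.40, fatty acid oxidation peroxisome -0.48, cholesterol synthesis srebp2 -0.12, lipid uptake lxr foam cell 0.076, lipogenesis 0.058, hypoxia response -0.21, er stress 0.12 and amino acid and organic ion transport -0.69. Within slide 2 they were proximal tubule S3 0.46, thick ascending limb 0.36, interferon response -0.27 and apoptosis ferroptosis necroptosis -0.18, and without both end arrays proximal tubule S1 S2 -0.21, collecting duct principal -0.18, collecting duct intercalated -0.027, fibroblast pericyte 0.21, resident macrophage 0.030, cytokine and nfkb inflammation 0.019, complement 0.10, extracellular matrix fibrosis 0.17, oxidative phosphorylation -0.10, fatty acid oxidation peroxisome -0.11 and amino acid and organic ion transport -0.17. With 1 array left out, the test turned in this way for fatty acid oxidation without wild-type 2 and for the fibroblast, complement and matrix lists without Ccr2-/- 3. The medians of these lists ranged from 0.011 to 0.29 for fatty acid oxidation peroxisome, from -0.24 to 0.086 for fibroblast pericyte, from -0.16 to 0.16 for complement and from -0.42 to 0.090 for extracellular matrix fibrosis. A further 49 list values turned direction with no call in either fit when 1 array was left out, and 49 did so in the other alternatives. Why these turned was not tested. Signal over background limits the dim probes, of which 10484 were not tested.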

Other observations

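Further genes, chosen after their values were seen, had groups that did not overlap at the probe with the smallest p but did not pass limma's adjusted p. In the Ccr2-/- group the values of the eosinophil-associated ribonuclease family were Ear1 -2.44 (SE 0.46), Ear2 -2.09 (SE 0.41), Ear10 -2.16 (SE 0.41), Ear12 -2.40 (SE 0.45) and Rnase2a -2.18 (SE 0.42). Because these paralogs are alike in sequence, their probes cannot be taken as separate observations. Retnla, a product of alternatively activated macrophages, was -2.59 (SE 0.68), Mucl1 -3.73 (SE 0.71), Sirpb1a -1.49 (SE 0.27), Klrb1a -1.81 (SE 0.33), Clec4b1 -1.40 (SE 0.33) and the macrophage elastase Mmp12 -0.92 (SE 0.26). F13a1, which encodes a subunit of coagulation factor XIII, was 1.21 (SE 0.24). Its second probe, well above background on 1 of 4 wild-type arrays, gave 0.90 (SE 0.35), with groups that overlapped. Limma adjusted p-values of these genes lay between 0.485 and 0.983.

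A test of neutrophil genes against the first hypothesis here was chosen after their values were seen. Fewer leukocytes of every kind are a hypothesis for the lower values of single genes of monocyte-derived cells, and it stays open. The neutrophil list did not fall: its mean log2 change was 0.50 (SE 0.14, 8 of 11 genes higher). That speaks against a fall that includes neutrophils, but the list was picked with its rise in view. The rise did not pass once adjusted (exact permutation p = 0.0286, 0.448 adjusted over the 47 lists). The test written first used 15 pan-leukocyte genes and could not decide. Their mean log2 change was -0.27 (SE 0.20, exact permutation p = 0.314, 0.400 adjusted over 4 such lists), with the bound, a fall of 0.5, within 2 SE. Fewer leukocytes of some kinds may be present, with 14 of the genes lower, Fcer1g at -0.12 and Cd52 at -0.47. But the fall lay in Ccr2-/- 3 and 4, at -0.58 and -0.31 centred per gene. Ccr2-/- 1 and 2 read 0.30 and 0.057, against 0.083 to 0.24 with wild-type marrow. Fewer non-classical monocytes stay open: the mean change of their 7 genes was -0.11 (SE 0.079, exact permutation p = 0.229, 0.400 adjusted). Their mean, centred per gene, was -0.25 on Ccr2-/- 4 and -0.098 to 0.094 on the other Ccr2-/- arrays. The genes went both ways (SD 0.36), with Spn at -0.71, Cd300e at -0.37 and Treml4 at -0.15 against Pou2f2 at 0.41 and Eno3 at 0.16. The bound of 0.5 set on their mean therefore does not decide. More tissue macrophages of the type that carries Folr2 stay open, since 8 other genes of such cells changed by 0.17 on average (SE 0.19, exact permutation p = 0.400, 0.400 adjusted). Their mean, centred per gene, was 0.33 on wild-type 2 and -0.30 to -0.12 on the other wild-type arrays. On Ccr2-/- 1 to 4 it was 0.40, 0.11, -0.23 and 0.066. Of the genes, 6 were higher and 2 lower, with Stab1 at 0.47 and Lyve1 at 0.44 but Gas6 at 0.0029 and Igf1 at -0.12. Other kidney cells also express some of these genes, such as Gas6, Igf1 and Lyve1.

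The second adipocyte list differed between the groups by 0.49 (SE 0.21, exact permutation p = 0.0571, 0.229 adjusted over the 4 lists). Of its 9 members, 7 were higher and 2 lower: Plin4 differed by 1.07 and Car3 by 0.94, but Aoc3 by 0.19, Lipe by -0.024 and Cebpa by -0.24.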
